A study of Mus musculus with 2 samples.

How the data were processed

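Islets of WT mice and of mice with a miR-203 transgene were measured, with 1 library per group. Per the labels, the mice were male, 8 weeks old and fasted for 12 hours, and the libraries were made with the 10x Genomics single-cell 3′ v2 kit. The labels' preparation texts name snap-frozen islets, TRIZOL extraction and a sort of intestinal goblet cells side by side, and the last does not match the islet tissue given elsewhere in the labels. The submitters' processing notes name FastQC, Trimmomatic and the mouse build mm10, without versions. The aligner, the counting tool and the annotation are not given in the sources used here.

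The deposited values are UMI counts per gene and droplet barcode, not normalised, per the file headers and the values themselves. Both matrices are unfiltered, with 737280 barcodes and 27998 genes in their size lines. The WT matrix was read whole, with 23027935 entries. The copy of the TG matrix held 547 whole entries and 1 broken line, which was dropped, and its gene list held 220 whole lines that equal the start of the WT list, so gene numbers were read through the WT list. Because the TG cells were not at hand, the planned comparisons of cell shares, expression, gene lists and miR-203 seed sites between the groups were not run, and the WT library was described alone, as had been laid down for that case before the data were examined. The contrasts between cell classes, the droplet comparison and the relation over cells were added after the data were seen.

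Barcodes with at least 10% of the UMIs of the 99th percentile of the top 3000 barcodes were called cells, a limit of 5610 UMIs. Of 4550 called barcodes, 3 had under 500 genes and 6 had over 15% mitochondrial UMIs, which left 4541. Scrublet, run in scanpy 1.11.5 with an expected rate of 6%, marked 2 cells (0.0440%), which were left out, and 4539 remained. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components and 15 neighbours were used for Leiden clustering (leidenalg 0.10.2) at resolution 0.5, which gave 15 clusters. Random seeds were fixed at 7. The analysis used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9 and matplotlib 3.10.9.

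A cluster was named from 20 marker sets fixed before the data were examined, by a rule set afterwards. A marker counted as raised at 2-fold over the 25th percentile of clusters with 10 CPM added, and a name needed 3 raised markers. A cluster stayed unnamed if 3 of Ins2, Gcg, Sst and Ppy each reached 10% of their highest cluster, if 2 classes each had 5 raised markers and 80% of their set raised, or if genes of another class or of the disallowed list led its top 10 genes. The beta-like class joins 6 clusters, of which some were led by immediate early genes such as Fos and Egr1, and the alpha-like class joins 2.

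Raw counts were summed over the cells of each class and given as CPM with exact Poisson intervals. A log2 ratio between classes was taken for genes of at least 20 CPM in either class, 4529 genes against alpha-like and 5580 against delta-like cells. Single genes are given as the plain ratio with its exact conditional binomial interval. List medians use CPM plus a pseudocount of 1. Both are relative to the median gene, which lay at log2 -0.39 against alpha-like and -0.88 against delta-like cells in CPM, at 0.32 and -0.01 without hormone and mitochondrial UMIs, and at -0.01 and 0.03 after scaling by the trimmed mean of M values. Each of 17 lists fixed in advance was described by its members beyond log2 0.58 either way and by the percentile of its median among 10000 random lists drawn from 20 expression bins, where 5 members were tested. Of the 442 fixed genes, 438 were in the gene list, the exceptions being Ero1b, Ighm, Trac and Trbc2. The lists of beta cell identity, islet hormones and disallowed genes hold genes that define the classes, so their values are no findings: against alpha-like cells their medians were 1.69, -4.39 and -3.39, and against delta-like cells 1.45 and -3.27, with 4 tested members for the last. The cell cycle list and the list of targets often named for miR-203 had 4 and 3 tested members in both contrasts and were not described.

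Named genes follow a rule fixed in advance: Ins1, Ins2, Iapp, Gcg, Sst, Ppy, Pyy, Mafa, Pdx1, Nkx6-1, Slc2a2, Ucn3, Xist and Ddx3y, and marker genes per class. A further gene of that rule is not reported here. The rule of the 2 highest and 2 lowest members per list had been set for the comparison of the groups, and its use on class contrasts was chosen after the data were seen. mt-Co1, Malat1, Gast, Cck and the other genes of the cluster they lead were named after their values were seen. PP-like cells were left out of the contrasts because their median insulin share was 16.6% of UMIs, against 2.59% in alpha-like cells.

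Tested on simulated data drawn at the real sums, with 200 changed genes among 3654 in the contrast with alpha-like and 3624 in that with delta-like cells, the steps placed 100.0% and 98.0% of genes changed by 2-fold beyond the band in the right direction, and 100.0% in both for 4-fold. They placed 0% and 1.14% of unchanged genes there. Of 200 unchanged lists, 3.0% and 3.5% passed the 2.5th or 97.5th percentile, and with the insulin share shuffled over cells 4.5% did. Intervals held the true ratio for 95.4% and 95.5% of genes. The simulated class sums were Poisson draws from 1 pooled rate per gene, without spread between cells, free RNA, doublets or the unlike insulin shares of the classes. Their coverage therefore follows from the setup, and the simulated shares do not cover such errors in the real contrasts. Gene positions come from GENCODE release M21 on GRCm38, the assembly that mm10 names, matched by gene ID for 27645 of 27998 genes (98.7%).

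The sum of 82588041 UMIs in beta-like cells allows a gene with no UMI up to 0.0363 CPM, taking 3 counts as the limit, and that of delta-like cells up to 2.45 CPM. Alternatives were other cell filters, clustering resolutions and treatments of doublets, other scalings, pseudocounts and floors, equal weight per cell, and thinning of each cell to 1 number of UMIs.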

Results

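Islets of 8-week-old male mice, fasted for 12 hours, were profiled by droplet single-cell RNA sequencing with 10x Genomics 3′ v2 chemistry. One group was wild type (WT, 1 library) and the other carried a miR-203 transgene that the labels place in beta cells (miR-203 TG, 1 library). The WT matrix held 118523180 unique molecular identifiers (UMIs, each standing for 1 captured transcript) over 27998 genes, and 88.4% of them lay in 4550 barcodes called as cells. After filtering, 4539 WT cells remained, with a median of 21649 UMIs (10th to 90th percentile 11109 to 36083), 3407 detected genes and 2.99% mitochondrial UMIs. Of the TG matrix, whose size line names 23580133 entries, the copy used here held the first 547, which cover barcodes 1 to 81 and 782 UMIs. The rest of it was not analysed here, so no TG cell enters any value. Every interval given is a 95% exact interval that covers counting error only, because each group has 1 library and no difference between the groups can be set against a replicate.

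The series set transgenic islets against WT islets, and the part of the TG matrix at hand allowed that only for droplets without a cell, which hold RNA released from the whole islet preparation. In these droplets insulin transcripts (Ins1 and Ins2 together) made up 13.2% of UMIs in the TG library (10.9 to 15.7, 103 UMIs), against 34.0% in WT droplets. Gcg, which encodes glucagon, the hormone of alpha cells, made up 8.06% (6.25 to 10.2, 63 UMIs) in TG and 2.19% in WT. Iapp, which encodes amylin, a peptide stored with insulin in beta cells, made up 9.08% (7.16 to 11.3) in TG and 5.87% in WT. Ppy (pancreatic polypeptide) stood at 4.22% (2.92 to 5.88) against 1.40%, Pyy (peptide YY) at 2.94% (1.87 to 4.38) against 0.484%, and Sst (somatostatin) at 0.384% (0.0792 to 1.12) against 0.249%. Mitochondrially encoded genes held 7.16% (5.45 to 9.20) in TG and 7.47% in WT, and Malat1, a nuclear RNA, 0.895% (0.361 to 1.84) and 1.15%. All of these are shares of 1 total, so a lower insulin share by itself raises every other share. This was not taken off, and the higher shares are not independent of the lower insulin share.

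The WT side of this comparison was divided into 2948 blocks of 81 consecutive barcodes with no barcode above 200 UMIs and at least 300 UMIs in the block, 3194606 UMIs in all. In the middle 95% of blocks, insulin lay between 28.2% and 41.9%, Gcg between 1.04% and 3.76%, Iapp between 4.13% and 7.90%, Ppy between 0.530% and 3.66%, and Pyy between 0 and 1.35%. None of the blocks reached down to the TG insulin share (lowest block 23.0%) or up to the TG Gcg share (highest block 6.67%), while 18 reached its Iapp share, 43 its Ppy share and 6 its Pyy share. The largest TG barcode held 110 UMIs, far below the 5610 UMIs at which a WT barcode was called a cell. Set against the first 81 WT barcodes instead, which hold 451 UMIs, the TG over WT ratio moved from 3.68 to 5.19 for Gcg, from 3.01 to 4.76 for Ppy, from 0.959 to 0.323 for mitochondrially encoded genes and from 0.779 to 2.02 for Malat1, which has 2 UMIs there. This comparison was chosen after the data were seen.

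**Figure D1:**
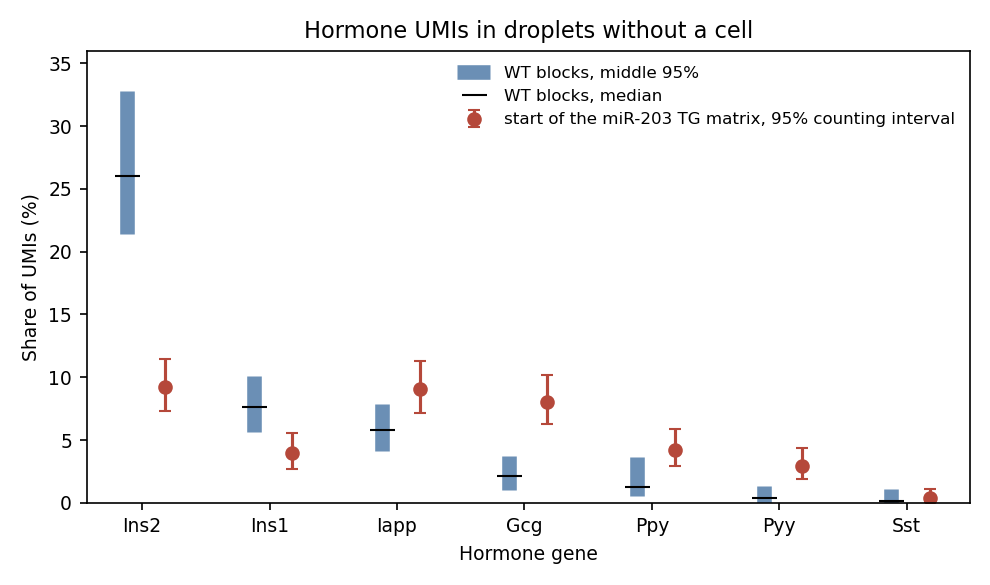
Share of UMIs (percent, y axis) of 7 hormone genes (x axis) in droplets without a cell. Blue bars span the middle 95% of 2948 WT blocks of 81 barcodes with the median as a black line, and red points give the 782 UMIs of the TG matrix at hand with exact 95% counting intervals. Ins2 lies at 9.21% in TG, below the lowest WT block (17.0%), and Gcg at 8.06%, above the highest (6.67%).

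The WT library carried the RNA of male islets, as labelled. Insulin transcripts alone took 42.6% of the UMIs in cells. Ddx3y, a gene of the Y chromosome (chromosome Y, 1260771 to 1286629), stood at 58.7 counts per 1000000 UMIs (CPM; 57.2 to 60.2), and Xist, the RNA of the inactive X chromosome, at 0.134 CPM (0.0732 to 0.225, 14 UMIs). The other Y-linked genes looked at were present as well, with Eif2s3y at 25.7 CPM, Uty at 12.7 CPM and Kdm5d at 3.93 CPM. The labels' extraction text describes sorted intestinal goblet cells, yet the 9 goblet cell markers fixed in advance together gave 273 of 104590073 UMIs (2.61 CPM), and Muc2, the main gut mucin, gave 4 UMIs. Among enterocyte markers, Vil1 (33.9 CPM) and Lgals3 (33.6 CPM) were detected, while Cdx2 gave 4 UMIs and Alpi, Cdx1, Sis and Car1 gave 0, which allows up to 0.0287 CPM each. No row of the gene list is named for Mir203, and mature microRNAs are not captured by a poly-A 3′ library, so the transgene product itself was not measured.

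Beta-like cells made up most of the WT library, with 3283 of 4539 cells (72.3%, 71.0 to 73.6). Alpha-like cells followed with 444 (9.78%, 8.93 to 10.7), then PP-like cells with 147 (3.24%, 2.74 to 3.80) and delta-like cells with 126 (2.78%, 2.32 to 3.32). Macrophage-like cells numbered 84 (1.85%, 1.48 to 2.29). A further 455 cells (10.0%, 9.17 to 10.9) in 4 clusters stayed unnamed because they carried markers of several classes or led with genes of none. These were 250 cells whose summed UMIs held 4 islet hormones, 127 with endothelial, mesenchymal and haemoglobin genes, 45 with acinar, B cell and proliferation genes, and 33 led by Gast and Cck. The 250 cells were led by Sst, Rbp4, Ly6h and Cd24a, which also led the delta-like cluster. The delta-like share may therefore leave out delta cells. Classes are named from markers fixed in advance, by a rule on those markers set after the data were seen. The doublet caller marked 2 of 4541 cells and has in effect not worked, so undetected doublets are not ruled out in any class.

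**Figure D2:**
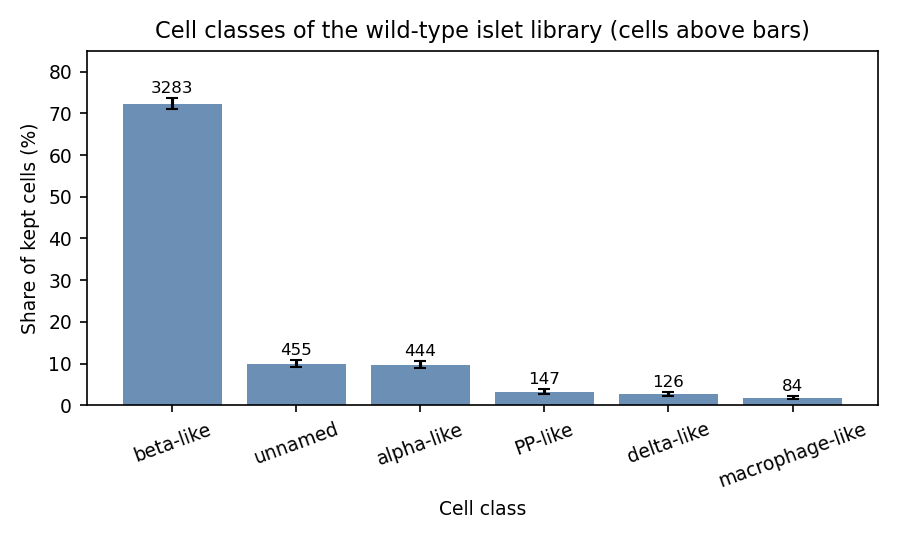
Share of the 4539 kept WT cells (percent, y axis) in each cell class (x axis), with the number of cells above each bar and exact 95% binomial intervals as error bars. Beta-like cells reach 72.3%, and no named class other than these exceeds 9.78%.

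The hormone genes that mark these classes were also counted in every other class. Ins2 (chromosome 7, 142678656 to 142743381 in GRCm38) stood at 371300 CPM in beta-like cells, 20918 CPM in alpha-like and 28238 CPM in delta-like cells. Ins1 (chromosome 19, 52264297 to 52265476) stood at 136280, 5690 and 7179 CPM in the same order. Gcg (chromosome 2, 62474530 to 62483650) reached 211120 CPM in alpha-like cells, with 1785 CPM in beta-like and 2009 CPM in delta-like cells, and Sst (chromosome 16, 23889573 to 23890958) reached 96850 CPM in delta-like cells, with 184 and 229 CPM in beta-like and alpha-like cells. In droplets of at most 200 UMIs, which hold free RNA, Ins2 stood at 263650 CPM and Gcg at 21890 CPM. Iapp (chromosome 6, 142298423 to 142303961) was high in beta-like cells (49175 CPM), intermediate in delta-like cells (26964 CPM) and PP-like cells (26998 CPM) and low in alpha-like cells (6679 CPM). If all Ins2 in alpha-like cells is free RNA, up to 4640 CPM of their Iapp is free RNA too, and in delta-like cells up to 6263 CPM. PP-like cells held 19.8% insulin and 0.136 Iapp UMIs per insulin UMI, below the 0.172 of WT droplets without a cell. The same assumption would make all of their Iapp free RNA, but it needs much of their RNA to be free, as WT droplets held 34.0% insulin. Gast, at 185 CPM in free RNA, was far lower in every cluster but the one it leads. The assumption therefore overstates free RNA in PP-like cells, and how much of their Iapp is free RNA is not known. Ppy and Pyy were each abundant outside PP-like cells: Ppy stood at 159600 CPM in PP-like, 32861 CPM in alpha-like and 34274 CPM in delta-like cells against 1930 CPM in beta-like cells, and Pyy at 35191, 28061 and 25329 CPM against 467 CPM. Free RNA, where Ppy stood at 14066 CPM and Pyy at 4864 CPM, gives alpha-like cells by the same reckoning up to 1116 and 386 CPM and delta-like cells up to 1507 and 521 CPM.

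Several genes of mature beta cells stood higher in beta-like than in alpha-like cells. The genes named here belong to the markers from which the beta-like class was named, so that direction is no finding. Ucn3, a peptide of mature beta cells, stood at 249 CPM in beta-like and 24.4 CPM in alpha-like cells, Slc2a2, the glucose transporter GLUT2, at 87.2 and 7.81 CPM, and Nkx6-1, a beta cell transcription factor, at 123 and 26.1 CPM. In droplets of at most 200 UMIs they stood at 183, 77.8 and 92.5 CPM, which by the same reckoning gives alpha-like cells up to 14.5, 6.17 and 7.34 CPM. Slc2a2 in alpha-like cells lay close to that level and is not read as expression, while Ucn3 and Nkx6-1 lay above it, with doublets not ruled out. Pdx1, a transcription factor that delta cells share, stood at 46.1 CPM in beta-like, 7.81 CPM in alpha-like and 80.9 CPM in delta-like cells, where free RNA gives up to 4.04 and 5.45 CPM. Relative to the median gene, Pdx1 in beta-like over delta-like cells lay at log2 0.07 (-0.22 to 0.37), so no difference between these classes is read from its CPM. Mafa, a transcription factor of mature beta cells, gave 10 UMIs in all cells together (0.0956 CPM), and a 3′ count depends on the transcript end that the counting annotation holds.

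Against alpha-like cells, the list medians of the unfolded protein response, cholesterol and lipid synthesis, insulin signalling, immediate early, mitochondrially encoded and secretory granule genes stood high in beta-like cells, and that of ribosomal proteins low. Of the 22 genes of the unfolded protein response, 16 lay over 1.5-fold above the median gene and 0 lay as far below, with a list median log2 ratio of 1.08 relative to the median gene. Ddit3, a transcription factor induced by protein folding stress, was among the highest (495 against 138 CPM, log2 2.23, 2.14 to 2.33), as was Edem1, which helps to dispose of misfolded proteins (59.5 against 19.8 CPM, log2 1.98, 1.73 to 2.23). Xbp1 (log2 -0.17, -0.23 to -0.11) and Manf (log2 0.13, 0.08 to 0.17) were the lowest. Of 24 ribosomal protein genes, 23 lay over 1.5-fold below the median gene, with a list median of -1.10. Rpl13 was the lowest (1183 against 4475 CPM, log2 -1.53, -1.55 to -1.51) and Rpl41 the highest (log2 -0.49, -0.50 to -0.48).

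Of the 11 tested genes of cholesterol and lipid synthesis, 6 lay above that band and 0 below (median 0.84), led by Acly, which makes cytosolic acetyl-CoA (282 against 102 CPM, log2 1.85, 1.75 to 1.96), and Insig1, a regulator of sterol synthesis (log2 1.77, 1.60 to 1.95). In insulin signalling, 8 of 13 lay above and 1 below (median 0.83), with the insulin receptor substrate Irs2 (log2 1.45, 1.25 to 1.65) and Igf1r (log2 1.44, 1.22 to 1.68) highest and Grb10, an adaptor that binds the insulin receptor, at -2.60 (-2.78 to -2.42). Immediate early and stress genes had 12 of 18 above and 2 below (median 0.83), from Fosb (763 against 181 CPM, log2 2.46, 2.38 to 2.54) and Egr1 (log2 2.39, 2.27 to 2.50) to Zfp36 (log2 -1.03, -1.15 to -0.90). Such genes led some of the clusters joined in the beta-like class. Their list again lay above all random lists when cells were clustered without the genes of the lists. That setting again gave 3283 beta-like cells, with 446 alpha-like cells against 444, and Fos still led some of the beta-like clusters. It therefore could not tell whether those clusters account for the list. Of 12 mitochondrially encoded genes, 11 lay above and 0 below (median 0.80), with mt-Co1 at 7362 against 4203 CPM, while 24 of 25 nuclear genes of oxidative phosphorylation lay within the band (median -0.10). The secretory granule list had 11 of 23 above and 2 below (median 0.49), with Sytl4, a granule docking protein, at 62.5 against 5.86 CPM, of which up to 4.47 CPM is free RNA if all Ins2 there is, so that its ratio is not given, and Pam, which amidates peptide hormones, at log2 -1.19 (-1.25 to -1.13). By the same reckoning, free RNA gives at most 11.6% (Irs2) to 32.7% (Fosb) of the alpha-like level of the other genes named as high in beta-like cells, and 10.1% (Irs2) to 48.5% (Sel1l) of the delta-like level of those named in that contrast, which was not taken off the ratios.

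The medians of the unfolded protein response, immediate early, mitochondrially encoded and secretory granule lists lay above all of 10000 random lists of the same size matched on expression, which describes this library and is no test over replicates. Cholesterol and lipid synthesis and insulin signalling lay at the 99.99th percentile of such lists and ribosomal proteins at the 1.86th. Glycolysis (median -0.04, 41.6th percentile), oxidative stress and hypoxia (0.01, 70.6th), interferon and antigen presentation (-0.11, 25.8th), p53 and apoptosis (-0.35, 3.92nd) and nuclear oxidative phosphorylation (66.2nd) lay between the 2.5th and 97.5th percentiles. Within the oxidative stress list the metallothioneins Mt1 (log2 2.33, 2.30 to 2.36) and Mt2 (1.88, 1.85 to 1.92) were high in beta-like cells and Gpx3, a secreted glutathione peroxidase, was low (-4.73, -4.77 to -4.69). The ribosomal list moved to the 17.0th percentile with a floor of 50 CPM. The median gene stood at log2 -0.39 in CPM and at 0.32 when hormone and mitochondrial UMIs were left out of the total, so all ratios here are relative to it.

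Against delta-like cells, the list medians of the unfolded protein response, cholesterol and lipid synthesis and mitochondrially encoded genes again stood high in beta-like cells, while that of ribosomal proteins did not stand apart. The unfolded protein response had 18 of 22 genes above the band and 0 below (median 1.27, above all random lists), with Sel1l, part of the machinery that removes misfolded proteins, at log2 3.14 (2.73 to 3.57) and Ddit3 at 2.73 (2.51 to 2.96). All 12 mitochondrially encoded genes lay above it (median 1.34, above all random lists). Cholesterol and lipid synthesis had 10 of 11 above (median 1.14, above all random lists), with Insig1 at 2.08 (1.69 to 2.49) and Hmgcs1, an early enzyme of sterol synthesis, at 1.96 (1.67 to 2.28). The secretory granule list had 14 of 22 above and 1 below (median 0.86, above all random lists), the exception being Chgb, the granule protein chromogranin B, at -1.58 (-1.64 to -1.51).

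Insulin signalling genes had 9 of 12 above the band (median 0.72, 99.97th percentile), with Irs2 at 1.31 (0.94 to 1.71). Immediate early genes had 8 of 18 above and 0 below (median 0.35, 98.8th percentile), with Fos at 2.33 (2.12 to 2.54), and this list moved to the 88.0th percentile when each cell was given equal weight. Ribosomal protein genes had 22 of 24 within the band (median -0.16, 27.4th percentile). Nuclear oxidative phosphorylation (0.19, 95.2nd), glycolysis (-0.15, 33.8th), p53 and apoptosis (0.12, 64.8th), interferon and antigen presentation (-0.28, 10.5th) and oxidative stress (-0.25, 4.14th) lay between the 2.5th and 97.5th percentiles. The delta-like sum rests on 126 cells and 1223796 UMIs, against 82588041 in beta-like and 7166307 in alpha-like cells.

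**Figure D3:**
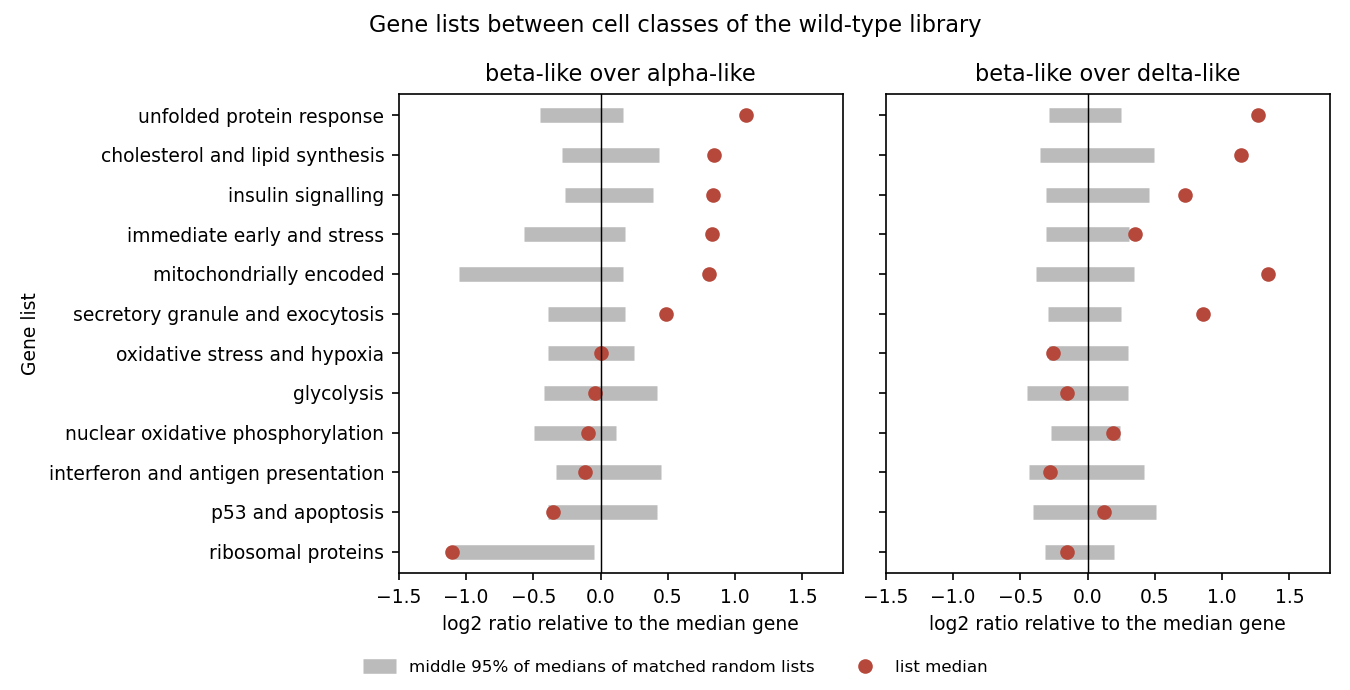
Median log2 ratio of each gene list relative to the median gene (x axis), beta-like over alpha-like cells on the left and beta-like over delta-like cells on the right, both within the WT library. Red points are list medians and grey bars the middle 95% of medians of 10000 random lists matched on expression. The unfolded protein response lies at 1.08 and 1.27, and ribosomal proteins at -1.10 and -0.16.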

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

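All tests in this part were chosen after the results were seen. The part of the TG matrix at hand, which holds no cells, showed more Gcg (8.06% of UMIs), Ppy (4.22%), Pyy (2.94%) and Iapp (9.08%) than the middle 95% of WT blocks of droplets without a cell, out of 13 genes and groups looked at. Insulin lay below every WT block, and a lower insulin share by itself raises all other shares by the same factor, so these are not independent results. The TG over WT ratios were unlike, at 6.08 for Pyy, 3.68 for Gcg, 3.01 for Ppy and 1.55 for Iapp. They stood at 0.959 for mitochondrially encoded genes and 0.779 for Malat1, so 1 common factor does not give them all. How much of each rise goes beyond that factor was not computed. Gast (3 UMIs, 0.384%, 0.0792 to 1.12, against 0.0188% in WT) and Cck (2 UMIs, 0.256%, 0.0310 to 0.921, against 0.0122%) lay above that range too, but 21 and 18 WT blocks reached these shares.

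Few UMIs do not account for Gcg or insulin: when 782 UMIs were drawn from each of 2447 WT blocks, the highest Gcg share was 6.01% and the lowest insulin share 24.7%, against 8.06% and 13.2% observed, but 9 draws reached the Iapp share, 32 the Ppy share and 3 the Pyy share, so for these few UMIs stay open. Nor does 1 droplet account for Gcg, since the Gcg share stayed at 7.61% or more whichever of the 9 droplets of 48 to 110 UMIs was left out, and in all 9 it lay above the WT droplet median of 1.92%. A lower share of beta cell RNA could be made up for by the other named WT classes. If free RNA has the profile of cells, this would give at most 0.377 Iapp UMIs per insulin UMI (their highest Iapp share is 2.70%). WT blocks reach 0.389, and the ratio stood at 0.689 (0.502 to 0.942). WT free RNA does not have that profile, with 5.87% Iapp and 34.0% insulin in droplets against 4.35% and 42.6% in cells. The bound therefore cannot exclude a lower share of beta cell RNA, which stays open. Delta-like cells have a ratio of 0.761 and come under the same assumption, and Sst was not clearly raised (0.384% against 0.249%). More RNA of the WT cluster with Gast and Cck, at 0.953, stays open too. It would bring the ratio to 0.283 at the Gast share seen, below the lower limit of 0.502, and to 0.719 at the upper limit of that share. This needs 28.1% and 84.7% of the free RNA to come from a cluster of 0.727% of WT cells. Genotype and preparation cannot be told apart with 1 library per genotype either, and that beta cells with the transgene may hold less insulin RNA relative to Iapp is a hypothesis that the TG cells themselves would test.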

How the results depend on the processing

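The class contrasts, the droplet comparison, the relation over cells and the settings on high doublet scores and on clustering without the list genes were added after the data were seen, while the other settings for class shares were fixed before. Of 27 class shares under other settings, 25 stayed within the main interval. The beta-like share moved to 69.2% with at least 200 genes and at most 25% mitochondrial UMIs, where 151 cells formed a cluster led by haemoglobin genes. The PP-like share moved to 2.37% when the 6% of cells with the highest doublet score were left out. The PP-like cluster stayed unnamed at resolution 1.0, and PP-like and delta-like cells stayed unnamed when clustered without the list genes, so these settings gave no value for them. Against alpha-like cells, 13 of 15 lists kept their side of the 2.5th and 97.5th percentiles in all 12 settings where they could be tested: ribosomal proteins moved to the 17.0th percentile at a floor of 50 CPM, and p53 and apoptosis to 0.47 at that floor and to 2.29 without a floor. Against delta-like cells, 12 of 14 did in 11 settings: immediate early genes moved to 88.0 and oxidative stress to 2.24 with equal weight per cell, and oxidative stress to 0.74 at a floor of 50 CPM. Both counts include the lists of beta cell identity and islet hormones, and that against alpha-like cells also the disallowed genes. These lists define the classes, so their keeping a side says little. Thinning left out 113 of 126 delta-like cells, so its values rest on 13. The cause of these moves was not tested. The TG over WT droplet ratios stayed within their counting interval in 46 of 50 pairs of item and setting, and with the first 81 WT barcodes as the comparison Gcg moved from 3.68 to 5.19, Ppy from 3.01 to 4.76, mitochondrially encoded genes from 0.959 to 0.323 and Malat1 from 0.779 to 2.02, while Gast and Cck, with 0 UMIs there, gave no value. Over beta-like cells, the median rank correlation of the unfolded protein response was -0.003, 0.013, -0.031, -0.028 and -0.172 in 5 equal groups from fewest to most UMIs, and that of mitochondrially encoded genes lay between -0.081 and 0.0016, against -0.21 over all cells. The settings for the comparison of TG with WT cells, for seed sites and for the whole library summed gave no value, since no TG cells were analysed. No paired analysis was possible because each group has 1 library.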

Other observations

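The tests in this part were all chosen after the results were seen, and the genes named here were chosen after their values were seen. A cluster of 33 WT cells (0.727%, 0.501 to 1.02) carried Gast, which encodes gastrin, at 13150 CPM (12899 to 13405) and Cck, which encodes cholecystokinin, at 8160 CPM (7963 to 8361), where no other cluster exceeded 12.4 and 11.4 CPM. Gast lies at chromosome 11, 100334407 to 100336996, and Cck at chromosome 9, 121489824 to 121495694 (GRCm38). The same cells held Pdyn, which encodes prodynorphin, at 650 CPM and Aldh1a3, a retinal dehydrogenase, at 112 CPM. Their Iapp level of 136780 CPM was above the 49175 CPM of the beta-like class, while Ins2 stood at 98209 CPM and Ucn3 at 26.4 CPM (16.3 to 40.3). Of the 33 cells, 26 held at least 10 Gast UMIs, against 0 of the other cells.

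Against doublets of the other clusters, 49 genes lay over 2-fold above every other cluster, where a mixture holds no more of a gene than its parents. Free RNA would give about 3.66 Gast UMIs per cell at this depth even if all UMIs of a cell were free RNA, against a median of 81. Cells carried over from the gut would hold insulin as other cells that are not endocrine do. Of the 33, 30 (90.9%, 75.7 to 98.1) lay above the 97.5th percentile of alpha-like cells (3.79% of UMIs). In the clusters with endothelial, macrophage and acinar genes, 9 of 127, 21 of 84 and 19 of 45 (42.2%, 27.7 to 57.9) did. But the last pools 25 cells led by B cell genes, with Ins2 at 16643 CPM, and 20 led by acinar genes, with Ins2 at 346400 CPM. Ins2 in that acinar part was above that of the Gast cells, so this comparison cannot speak against gut cells. That these are islet endocrine cells that carry Gast and Cck RNA is a hypothesis, and cells carried over from the gut stay open. No biological explanation was tested, because the design gives no group for it.

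The summed UMIs of an unnamed cluster of 250 cells held Ins2 at 123180 CPM, Gcg at 34950 CPM, Ppy at 40208 CPM and Sst at 15933 CPM. Its leading genes were Sst, Rbp4, Ly6h and Cd24a, as in the delta-like cluster. In 4 of the cells Gcg, Sst and Ppy were each above 3 times the level of a droplet that holds only free RNA. This limit is strict, since the summed Gcg and Ppy of the cluster themselves lie below it, so a low count says little about these hormones. That count does not bear on doublets either, since a pair of cells need not hold all of these hormones. Doublets with delta-like cells would hold at least the Sst of those cells, and the median was 293.5 UMIs per cell against 788.5, but a partner under the limit of 5610 UMIs could hold less. Its median of 23128 UMIs, 2.67 times that of delta-like cells, goes towards mixtures, though beta-like cells reach a median of 23133 UMIs. It had 0 genes over 2-fold above every other cluster. A cluster that shares its genes with another has few such genes in any case, as in 5 of 6 beta-like clusters, so this count says little. Doublets therefore stay open, with a median doublet score of 0.112 that equals that of a beta-like cluster and exceeds the 0.0216 of delta-like cells. With the 6% of cells with the highest doublet score left out, the cluster of this kind held 195 cells. No biological explanation was tested.

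Among the 84 macrophage-like cells, insulin transcripts took a median of 2.65% of UMIs, close to the 2.59% of alpha-like cells, but 18 cells held over 10% and the highest 60.2%. The unnamed cluster with 4 hormones in its sum, clustered on its own, fell into groups of 94, 89 and 67 cells, each led by Sst. In that order, Ins2 stood at 27107, 244370 and 71774 CPM, Gcg at 75360, 9368 and 20425 CPM, and Sst at 22298, 12333 and 13035 CPM. The one with acinar and B cell genes split into 25 cells led by B cell genes such as Ly6d and Cd79b and 20 led by Ctrb1 and Cela2a, and the one with endothelial genes into 71 cells led by Cxcl13 and Rgs5, 42 led by haemoglobin genes with Esm1 and Plvap, and 14 led by Jchain.

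Across 2954 beta-like cells thinned to 7437 non-hormone UMIs each, the insulin share was set against each gene's part of the non-hormone UMIs. For nuclear oxidative phosphorylation genes that part rose with the insulin share, with a positive rank correlation for 25 of 25 genes. The RNA amount per cell was not measured. The median rho was 0.21 (middle 95% of random lists -0.03 to 0.10), and it lay between 0.084 and 0.185 in 5 equal groups of cells by total UMIs. Glycolysis genes had a median of 0.11 (98.5th percentile; 0.019 to 0.136 within the 5 groups), mitochondrially encoded genes -0.21 (12 of 12 below 0) and the unfolded protein response -0.08 (15 of 21 below 0). Within the 5 groups the mitochondrially encoded median lay between -0.081 and 0.0016, and that of the unfolded protein response between -0.031 and 0.013 in 4 groups and at -0.172 in the group with the most UMIs. Immediate early genes had a median of 0.06 over all cells but lay between -0.19 and -0.05 within the 5 groups, and the insulin share itself rose with total UMIs (rho 0.53). These are relations over cells of 1 library, which are not replicates, over 13 lists.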
